A study of Caenorhabditis elegans with 2 samples.

How the data were processed

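The series measured where the TBP-like factor TLF-1 lies on the Caenorhabditis elegans genome, by chromatin immunoprecipitation and sequencing. Per the labels, whole young adults at 65.5 hours were used, grown from L1 larvae starved after bleaching, with the sexes pooled. The strain carries an integrated tlf-1 transgene whose product ends in an EGFP and FLAG tag, with unc-119(+) as rescue marker, and the immunoprecipitation used an antibody against GFP. There were 2 biological replicates of 1 group and no other group, so the comparisons are between replicates, between classes of genes and between observed and randomly shifted peaks. The labels give the replicates separate biosample records, and they do not say whether their cultures were grown at different times.

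The authors deposited 4 peak lists on assembly ce11, per the labels. Per the README files, each replicate list was derived from that replicate's alignments and a control file that both replicates shared, a pooled list from both sets of alignments and the same control, and the set thresholded on the irreproducible discovery rate (the IDR set) from the other 3 lists. The peak caller, the aligner, the IDR threshold and the read depth are not given in the sources used here, so depth is unknown and no interval below reflects it. The deposited signal value of a peak is the authors' own, and it was used only to rank and describe peaks within a list. The deposited -log10 q-value was used to describe the lists, and the deposited summit offset gave each peak's summit. Read-level and coverage tracks were not used here.

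Gene models were those of Ensembl release 115 on WBcel235, the same assembly as ce11, and sequence came from the RefSeq copy of that assembly. A promoter window ran from 500 bp upstream to 100 bp downstream of the annotated start of a protein-coding gene, and a gene had a promoter peak when an IDR summit lay in it. One summit may fall in the windows of neighbouring genes. Annotated starts of trans-spliced genes lie downstream of the true transcription start. A gene was in operon-like position when its start lay within 500 bp downstream of the end of a protein-coding gene on the same strand. Chromosome centres were the middle of 3 equal parts by length of each autosome. Non-coding genes had a peak when one lay within 100 bp, and classes with at least 20 genes were tested.

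Peaks were compared with 1000 circular shifts within each chromosome, which keep their spacing. These are permutation tests, one-sided except for gene lists, and the smallest p they can give is 0.001 one-sided and 0.002 two-sided. The overlap of all deposited peaks used 100 shifts, with a smallest p of 0.0099. Classes of genes were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment and a call at an adjusted p under 0.05. Shares carry 95% Wilson intervals, which cover counting error only. The median summit position carries a 95% bootstrap interval from 10000 resamples of peaks, and the rank correlation one from 1000. Motifs were sought on either strand in the 200 bp around promoter summits, against 1 window per peak from promoters without a peak within 1000 bp, at the same distance from the gene start and with a GC content within 2.5 percentage points.

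The 28 gene lists, the 14 motifs, the tests, most alternatives and the rule for naming genes were set before the data were examined. The rule names the genes whose promoter windows hold one of the 20 strongest IDR peaks, up to 4 members with the strongest peaks of each list called higher, up to 2 of each list called lower, and tlf-1, unc-119 and tbp-1 always. Motifs that were not called are given as a count. Alternatives covered the overlap definition, each replicate alone, the stronger part of the IDR set, other promoter windows, all transcript starts, peaks counted once, other control windows and leaving out the 20 kb around tlf-1 and unc-119. The code was tested on simulated data. With peaks favouring lists 6-fold among the 19973 coding genes, 247 of 250 favoured lists were called, and 19 of 1150 others. The favoured lists had 57 to 80 genes, so recovery of smaller lists or weaker differences was not tested. A planted motif was called in 20 of 20 runs. It was the NRF1-like motif, planted in random sequence and in a larger share of windows than held it at the peaks. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.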

Results

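Binding of tagged TLF-1 in young adults was recorded as 24495 peaks in replicate 1 and 23453 in replicate 2, with 28153 in the pooled list and 1880 in the IDR set. The IDR set covered 0.673% of the genome, against 10.6% for the pooled list. All 1880 IDR peaks were rows of the pooled list, and they were its 1880 strongest. At 85.2% of them the -log10 q-value sat at the maximum of that list, so that value does not rank them.

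The replicates shared most of their strongest peaks. The strongest IDR peak, in the promoter of the ribosomal protein gene rpl-3, ranked 1 in both replicates, and the next, in front of tasp-1, ranked 2 in replicate 1 and 3 in replicate 2. Of the 1880 strongest peaks of replicate 1, 1312 (69.8%) overlapped one of the 1880 strongest of replicate 2 by at least 1 bp, and 1291 (68.7%) did in the other direction. Shifted peaks overlapped at 1.49% on average (permutation p = 0.001, the smallest that the shifts can give). Both lists were called against one control file, and shifts do not give the overlap that a shared control alone would produce. Over all deposited peaks the share was 53.2%, against 17.2% for shifts. Signal at 1879 IDR peaks found in both replicates had a Spearman rho of 0.636 (95% bootstrap interval 0.605 to 0.666) and a Pearson r of 0.768 on log2 values, across peaks, which are not independent replicates. These peaks were not chosen independently of the replicates. They were the strongest of the list pooled from both, in a set that the authors thresholded on the irreproducible discovery rate. Of the IDR peaks, 1280 (68.1%) were among the 1880 strongest of both replicates and 40 among those of neither.

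**Figure D1:**
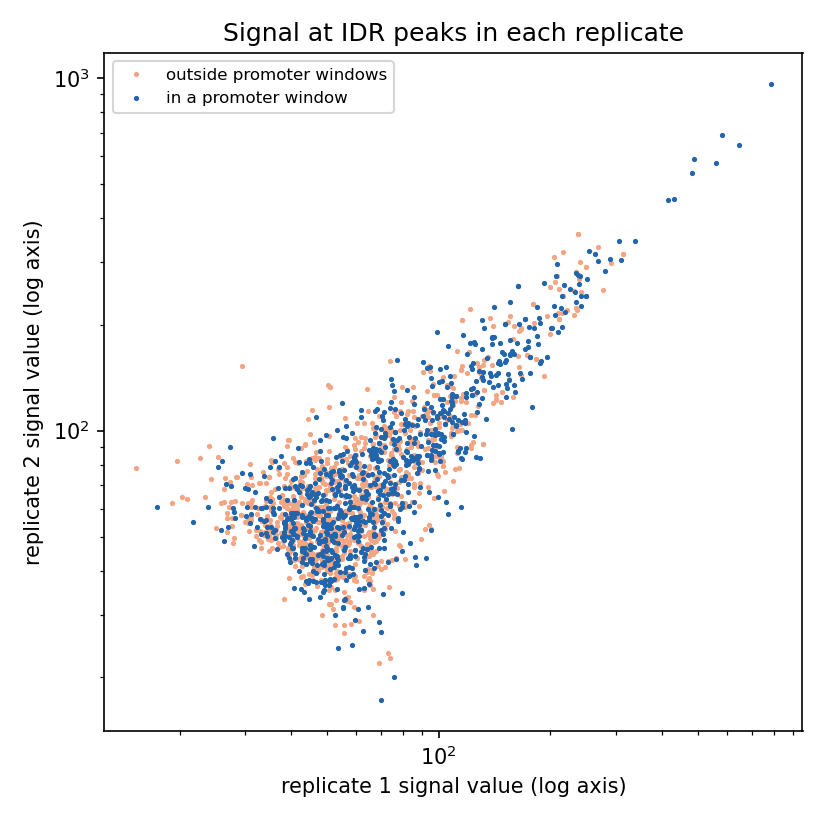
Signal value of each IDR peak in replicate 1 (x axis) and replicate 2 (y axis), both on log axes in the authors' units, with blue points in a promoter window and orange points elsewhere. Points lie close to a line at high signal and spread widely at low signal, with a Spearman rho of 0.636 over 1879 peaks.

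TLF-1 peaks gathered just upstream of gene starts. Promoter windows of protein-coding genes held 836 of the 1880 IDR summits, or 44.5% (95% Wilson interval 42.2 to 46.7), which was 3.97 times the 11.2% of shifted peaks (permutation p = 0.001, the smallest possible). With a window of 1000 bp upstream and 500 bp downstream the share was 57.5%, or 2.20 times that of shifts. Among 1166 summits within 1000 bp of a gene start, the median lay at -171 bp (bootstrap interval -181 to -157), with quartiles at -322 and -18 bp, and 78.0% were upstream. Each summit was given a single place, in the order promoter window, coding exon, untranslated exon, intron, non-coding RNA gene and intergenic. Of all 1880 summits, 5.53% fell in coding exons against 23.1% of shifted ones. Untranslated exons held 5.48% against 3.53%, and introns 15.9% against 33.4%. Non-coding RNA genes outside those places held 4.04% against 0.715%, and 24.6% were intergenic against 28.1%. Promoter windows took 44.5% of summits and 11.2% of shifted ones, which leaves fewer summits for the other places. The lower intergenic share thus does not show a deficit among summits outside promoter windows.

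**Figure D2:**
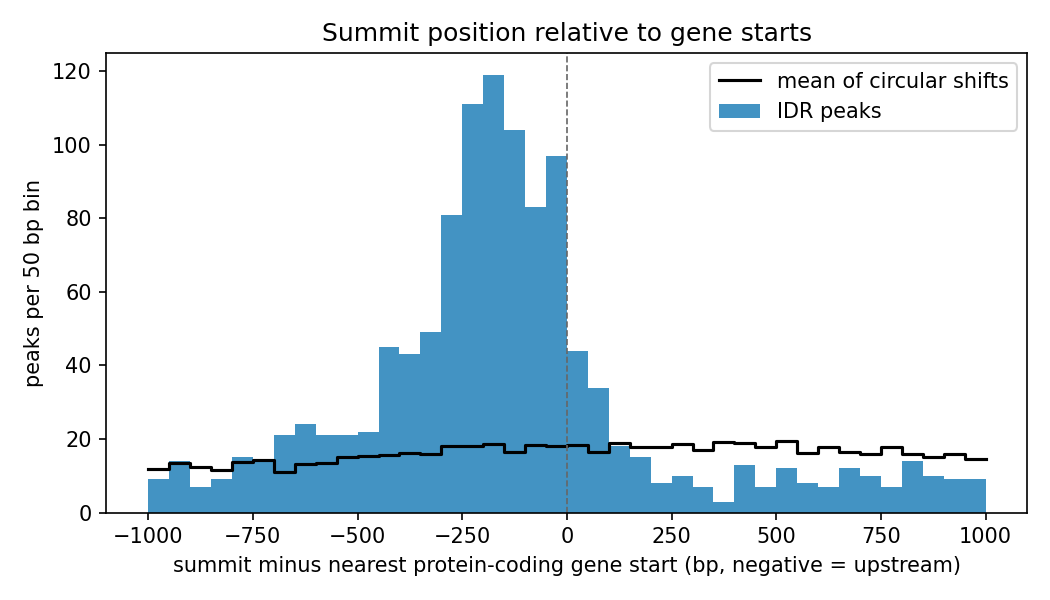
Number of IDR peaks (bars) per 50 bp bin of distance from the summit to the nearest protein-coding gene start, negative being upstream, with the mean of 20 circular shifts as a black line. The bars stand above the line mainly upstream of the start, around the median of -171 bp.

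Of the 20 strongest IDR peaks, 16 were in promoter windows, and 6 of these were windows of ribosomal protein genes. The first, with a signal of 1737.8, was centred at position 3867576 of chromosome III (peak 3867165 to 3867783), 278 bp upstream of rpl-3 (WBGene00004414), which encodes a protein of the large ribosomal subunit. Several of the peaks lay in the windows of divergent or neighbouring genes at once. Ribosomal protein genes among them were rpl-20, whose peak also lay in the window of Y17G9B.5, rpl-35, rpl-15 with K11H12.8, rps-19 with hsr-9, and rpl-12 with lin-54, which encodes a DNA-binding subunit of the DREAM complex. The others were tasp-1, Y22D7AL.10, cdc-48.1 (a AAA ATPase), drr-2 with set-16, cox-5A (a cytochrome c oxidase subunit), cct-8 (a chaperonin subunit) with Y55F3AR.2, hsp-1 (a constitutive heat shock protein), sec-61.G (a subunit of the protein translocon), wip-1, and rib-2 with the tubulin gene tbb-1. Of the remaining 4, 1 lay within ppfr-1 on chromosome I and 3 on X.

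Promoter peaks were found at 1054 of 19973 protein-coding genes (5.28%), and 12 of the 28 gene lists had them more often than other coding genes. Cytosolic ribosomal proteins had the highest share with this window, with peaks at 46 of 80 genes (57.5%, Wilson interval 46.6 to 67.7), an odds ratio of 25.3 (Fisher's exact test, adjusted p = 1.45e-36). That share depended on the window: with 250 bp upstream it was 12 of 80 (odds ratio 5.01), below germline markers (25.4%), splicing factors (22.8%), proteasome (21.2%), cell cycle genes (20.4%), ribosome biogenesis (4 of 20) and oxidative phosphorylation (15.5%). With each peak counted once it was 30 of 80 (37.5%, odds ratio 14.4). Germline and oocyte markers followed with 21 of 59 (35.6%, interval 24.6 to 48.3, odds ratio 10.1, exact test adjusted p = 8.66e-12), among them mex-1, puf-9, spn-4 and pos-1, which encode RNA-binding proteins. The peak of pos-1 also lay in the window of vha-18.

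Genes of protein folding, energy supply and RNA processing were also over-represented. Chaperones had promoter peaks at 20 of 68 genes (29.4%), with cct-8, hsp-1, dnj-13 and hsp-110 the strongest. Their odds ratio of 7.60 was 4.31 with 250 bp upstream (9 genes) and 4.51 with each peak counted once (11 genes). Oxidative phosphorylation had them at 19 of 71 (26.8%), led by cox-5A, cox-5B, atp-1 and ndub-8. Splicing factors had them at 15 of 57 (26.3%), led by rsp-6, by rsp-1 and rsp-2, which share a peak, and by prp-40. Vacuolar ATPase subunits had peaks at 6 of 20 genes, with vha-18, vha-2, vha-1 and vha-12 the strongest, and ribosome biogenesis factors at 6 of 20, with fib-1, pro-1, nol-58 and nol-10. The largest adjusted p of these 5 lists was 0.00111 in Fisher's exact test. The vacuolar ATPase call ended with a window of 250 bp upstream (odds ratio 3.12, adjusted p = 0.191, exact test).

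Proteasome subunits had promoter peaks at 8 of 33 genes (24.2%), with rpn-3, rpn-2, pbs-1 and rpn-11 the strongest. The peak of rpn-3 also served hsp-110. Cell cycle and replication genes had them at 12 of 54 (22.2%), with cdc-48.1, pcn-1 (the replication clamp), mcm-2 and mcm-4, though cdc-48.1 acts in protein turnover as well. Translation factors had them at 8 of 41 (19.5%), with iff-2, eif-3.C, eef-2 and eef-1A.1. General transcription factors and RNA polymerase subunits had them at 9 of 72 (12.5%), with rpb-11, rpac-19, taf-4 and taf-12 (adjusted p = 0.0217, exact test). Mitochondrial ribosomal proteins had them at 8 of 70 (11.4%), with mrpl-28, mrpl-32, mrpl-13 and mrpl-55 (adjusted p = 0.0477, exact test), a call that ended without replicate 1, where the odds ratio was 1.81, with a window of 250 bp upstream (2.64), in the 1280 peaks strong in both replicates (1.12), and in the stronger 940 IDR peaks (0.449).

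The genes of 6 lists had promoter peaks less often than other coding genes. Chemoreceptors had them at 6 of 1310 genes (0.458%, odds ratio 0.0773, adjusted p = 9.46e-23, Fisher's exact test), the strongest at sri-5 and srh-16. Neuron markers had none among 129 genes, which allows a share of up to 2.89% (Wilson). F-box and MATH domain proteins had 5 of 395, including fbxb-85 and fbxb-72, C-type lectins 3 of 240, including clec-126 and clec-87, nuclear hormone receptors 5 of 269, including nhr-68 and nhr-47, and cuticle collagens 2 of 172, col-38 and col-71. Against shifted peaks none of these 6 was called. Shifts reached 11.8 chemoreceptor genes where 6 were observed (adjusted p = 0.210, permutation) and 1.39 neuron markers where none was. The other 4 lists were at or above the shifts: nuclear hormone receptors 5 against 2.51, F-box and MATH 5 against 4.62, C-type lectins 3 against 2.56 and collagens 2 against 1.88. The lists were thus below other genes, and there is no sign that these 4 were below random positions. The calls of neuron markers, nuclear hormone receptors and cuticle collagens ended in the stronger 940 IDR peaks, where there are fewer peaks and the odds ratios were 0.119, 0.347 and 0.180, against 0.0688, 0.337 and 0.210 with all. The call of nuclear hormone receptors also ended without replicate 1 (odds ratio 0.435), that of collagens with the narrower window (0.162), and both without operon-like genes (0.411 and 0.260). Other settings lowered these odds ratios and kept the calls: nuclear hormone receptors had 0.103 with 250 bp upstream and 0.206 without replicate 2, collagens 0.107 without replicate 2 and 0.134 with each peak counted once, and C-type lectins 0.116 with 250 bp upstream and 0.128 in the stronger 940, against 0.225. Collagens had 0.315 with 1000 bp upstream, and neuron markers 0.107 with 250 bp upstream, both still called.

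The other 10 lists were not called. Core histones had promoter peaks at 6 of 72 genes, aminoacyl-tRNA synthetases at 4 of 32, and actins and tubulins at 3 of 18, and these 3 lists exceeded shifted peaks. Promoter windows of all coding genes also did, with 44.5% of summits against 11.2%, so this does not set the 3 lists apart from other genes. Synthetases also passed Fisher's exact test without replicate 2 (odds ratio 3.44), and actins and tubulins in the stronger 940 peaks (6.23) and with a window of 1000 bp upstream (5.14). Sperm genes had peaks at 2 of 85, hypodermis markers at 2 of 75, intestine markers at 1 of 56 and homeobox factors at 1 of 85. Muscle markers (36 genes), linker histones (9) and vitellogenins (6) had 0. Odds ratios of the sperm, hypodermis, intestine, homeobox and muscle lists were below 1, from 0.213 to 0.491. Wilson intervals of these lists, and of linker histones and vitellogenins, reached above the overall 5.28%. A lower share in them was thus neither shown nor excluded.

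**Figure D3:**
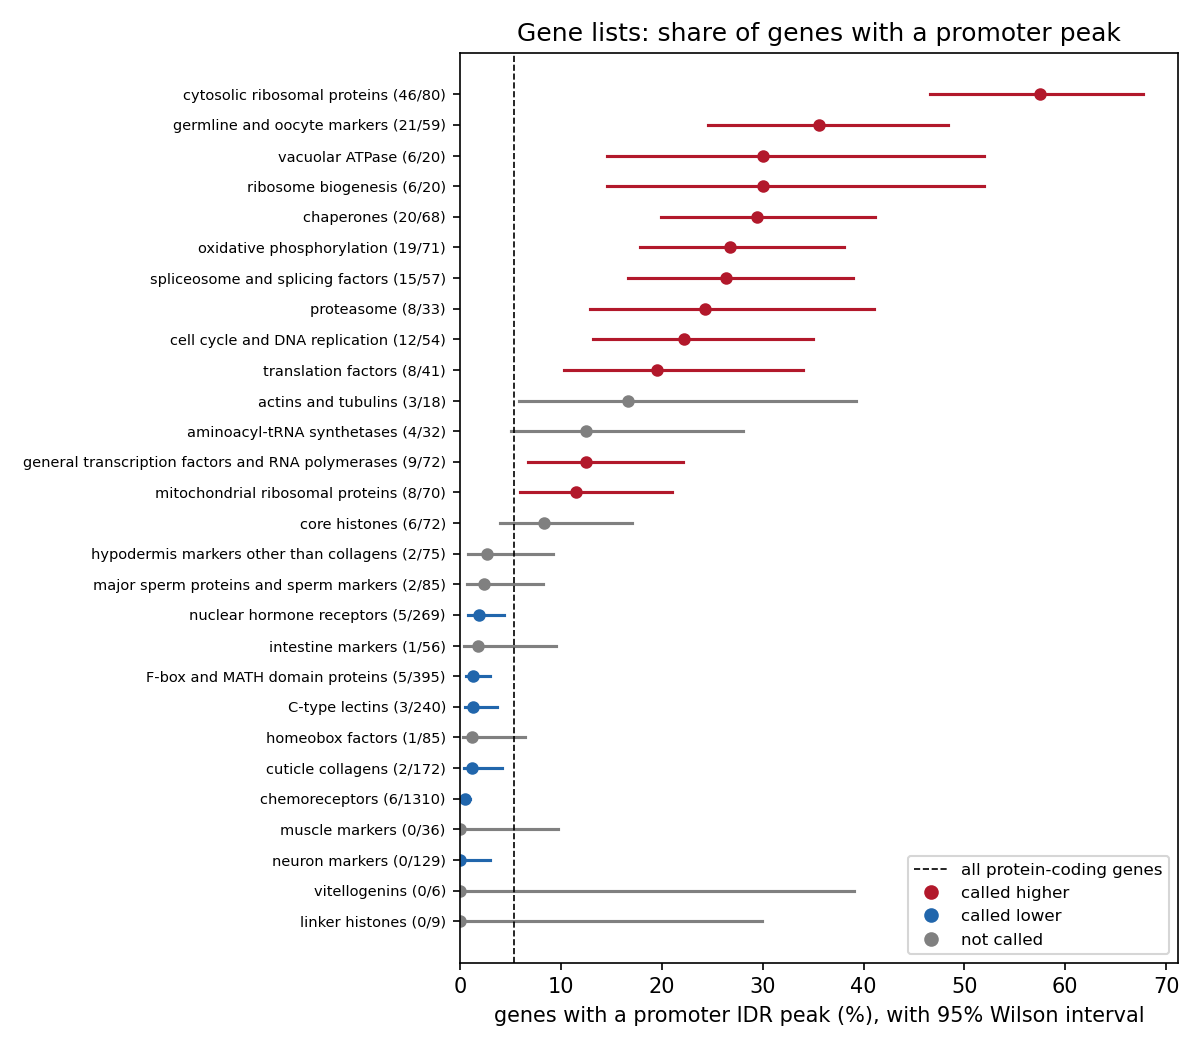
Share of genes with a promoter IDR peak (x axis, percent) for each of 28 gene lists (y axis, with counts), points being the share and bars the 95% Wilson interval, and the dashed line all coding genes at 5.28%. Red lists were called higher, blue lower and grey neither, with cytosolic ribosomal proteins at 57.5% at the top.

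Genes on X had fewer promoter peaks than those on autosomes. A promoter peak was present at 66 of 2731 X-linked genes (2.42%) and 988 of 17242 autosomal genes (5.73%), an odds ratio of 0.407 (p = 4.21e-15, two-sided Fisher's exact test). Chromosome III had the highest share, 9.24%. Peaks outside promoters were not scarce on X: there were 10.3 per Mb there, and 75.2% of X peaks were outside promoter windows, against 49.8% on chromosome I and 55.3% on V. In the autosomes, genes in the central of 3 equal parts had promoter peaks at 6.48% and those in the outer parts at 5.27% (odds ratio 1.25, p = 9.39e-04, Fisher's exact test). Genes in operon-like position had them at 6.25%, others at 5.06% (odds ratio 1.25, p = 0.00456, Fisher's exact test), a contrast that varied with the setting. It was not called with a gap of at most 250 bp (odds ratio 1.03, exact p = 0.763), in the stronger 940 peaks (1.04) or in the 1280 peaks strong in both replicates (1.19). It was larger with a window of 250 bp upstream (1.87, p = 3.59e-12, exact test) and without replicate 1 (1.39).

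**Figure D4:**
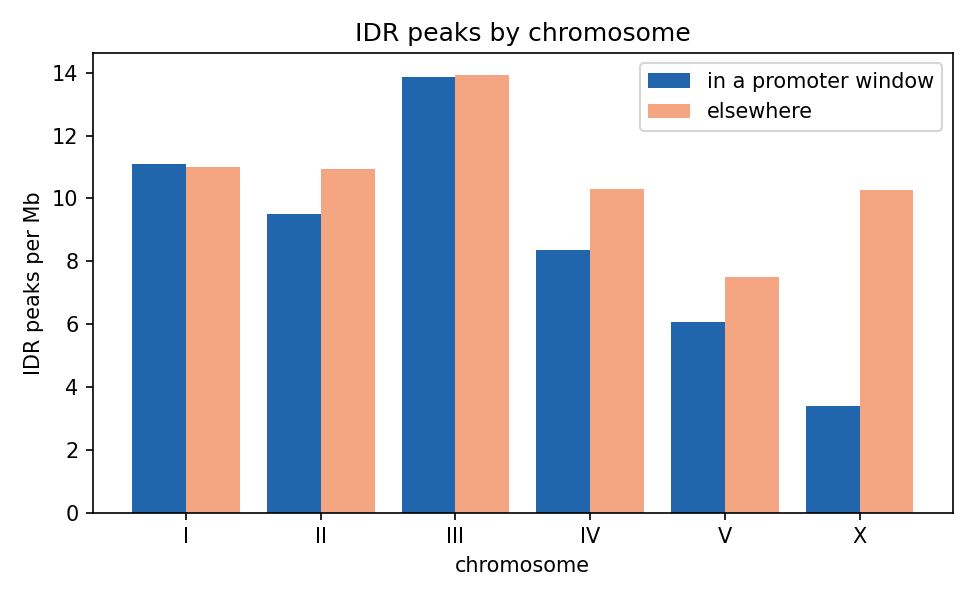
IDR peaks per Mb (y axis) on each chromosome (x axis), blue bars in promoter windows of coding genes and orange bars elsewhere. X has the fewest promoter peaks per Mb, 3.39, and 10.3 elsewhere.

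Several classes of small RNA genes carried peaks. No untagged strain was analysed, so signal that does not depend on TLF-1 was not separated, at these genes or at the coding genes above. Spliced leader RNA genes, which supply the leader added in trans-splicing, had a peak at 11 of 30 genes (36.7%, against 1.30% for shifts), snoRNA genes at 83 of 346 (24.0%), tRNA genes at 138 of 612 (22.5%, against 1.07%), and snRNA genes at 17 of 99 (17.2%). MicroRNA genes had one at 16 of 261 (6.13%) and genes annotated only as ncRNA at 367 of 7764 (4.73%). These 6 of 10 classes were called, each at a permutation p of 0.001. Genes close together can share a peak, so the counts are of genes and not of separate peaks. For example, mir-1831 lies within sup-39, and both counted as snRNA genes with a peak. All 11 spliced leader genes with a peak belonged to the sls-2 series, so peaks in that class were seen for this series only. Whether reads can be placed uniquely at the other spliced leader genes, or at rRNA genes, was not examined. The lack of a peak there does not show absence of binding. The piRNA genes had peaks at 33 of 15363, where shifts gave 162 on average, and rRNA, lincRNA and antisense genes were not called, though lincRNA genes passed within 500 bp. With only peaks outside coding promoter windows the same 6 classes passed, tRNA genes at 19.4%, snoRNA genes at 18.5% and ncRNA genes at 3.05%. With the stronger 940 peaks alone, 38 tRNA genes (6.21%), 9.09% of snRNA genes, 2.68% of microRNA genes and 2.52% of ncRNA genes had one, all still called. In the 1280 peaks strong in both replicates these were 11.4% of tRNA, 10.1% of snRNA and 3.45% of microRNA genes, and within 500 bp 10.7% of microRNA genes, also called.

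Of the 14 motifs, 2 were more frequent at promoter summits than in matched controls. The E2F-like motif occurred in 218 of 826 windows (26.4%) and in 81 matched controls (9.81%), an odds ratio of 3.28 (Fisher's exact test, adjusted p = 1.55e-17), and the NRF1-like motif in 7.38% against 3.27% (exact test, adjusted p = 0.00180). With controls matched on distance only, whose GC content was 34.6% against 41.2% at peaks, these odds ratios were 5.18 and 6.91. The TATA box, the element bound by TBP, was less frequent, 7.63% against 11.4% (exact test, adjusted p = 0.0408), a call that ended with another draw of control windows (odds ratio 0.669 in place of 0.645) and without replicate 1 (0.742), and was 0.393 with controls matched on distance only. So was the CCAAT box, 28.3% against 36.4% (exact test, adjusted p = 0.00240), a call that ended without replicate 2 (odds ratio 0.782), with 100 bp windows (0.834) and with controls matched on distance only (0.842). Both calls also ended in the stronger 940 peaks (0.727 for TATA and 0.803 for CCAAT) and in the 1280 peaks strong in both replicates (0.606 and 0.724). The remaining 10 motifs were not called. Of 2080 6-base words, 218 were more and 221 less frequent at peaks, the first being GCGCCA, in 20.7% of peak windows and 4.84% of controls. The next words, ACGCGC, GCGCAC and GGCGCA, also hold the pair CG, as do the E2F-like and NRF1-like motifs. Controls were matched on GC content and not on the pair CG, so these 2 motifs were not shown to stand apart from such words.

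No IDR peak lay over the tagged gene itself. The tlf-1 gene (WBGene00006577, chromosome I, 8697504 to 8701973, minus strand) had 5 pooled peaks over it, the best ranked 4163, and 2 IDR peaks within 20 kb, ranked 502 and 1254. The pooled list held 28 peaks within 20 kb of it, against 20 for tbp-1, the gene for TBP (chromosome III, 7384033 to 7386124), which also had 2 IDR peaks in that range. The unc-119 gene (chromosome III, 10902641 to 10908935) had 4 pooled peaks within 20 kb and no IDR peak. None of the 3 had an IDR peak in its promoter window.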

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

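Depth is unknown, so what it limits could not be assessed, and each replicate alone was represented by its 1880 strongest peaks. Use of the strongest pooled peaks is void, since they are the IDR set, and a comparison between replicates cannot leave one out. The subset of 1280 IDR peaks among the strongest of both replicates, the tests on peaks outside promoters and the tagged locus in single replicates were chosen after seeing the data. The replicate overlap, promoter share, X and centre contrasts, count of lists called higher and count of non-coding classes kept direction and side of the threshold, or stayed within 1.5 times, in all alternatives run. Without each replicate the median summit position ranged from -167 to -159 bp and IDR-sized sets held 1 to 3 peaks within 20 kb of tlf-1. In the stronger part of the IDR set rho was 0.710, the median position -191 bp, the operon-like odds ratio 1.04, lists called lower 3 and motifs called 2. In the subset of 1280 the median was -180 bp, the operon-like odds ratio 1.19 and motifs called 2. The nearest summit gave a rho of 0.593, a gap of 250 bp an operon-like odds ratio of 1.03, and circular shifts 0 lists called lower. Mitochondrial ribosomal proteins turned to an odds ratio of 0.449 in the stronger part. Linker histones, with 0 of 9 genes, changed side of 1 only through the value added to empty cells. Their odds ratio was 0.944 with all IDR peaks and 0.972 without replicate 2. It passed 1 without replicate 1 (1.01), in the stronger part (1.63) and in the subset (1.32). The same was seen with the narrow window (1.47), without operon-like genes (1.10) and with peaks counted once (1.22). Other causes were not tested. Of 73 named genes, 71 had their peak among the 1880 strongest of both replicates; mrpl-13 and col-71 did not. Of the 10 motifs not called, 2 had an odds ratio of 1, and the other 8 changed direction in 24 of 55 alternatives with a direction. With controls matched on distance only, the GC box (odds ratio 2.48) and T block (0.551) were called, in the directions they had before. No paired analysis was possible because there is 1 group.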

Other observations

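The tests of chance concentration, tRNA genes, transcript output, tlf-1 copies and unc-119 copies, and the families and 6-base words below, were chosen after the results were seen. The test of chance first used the 100 strongest distal peaks alone, which decided nothing, and the scan of all cuts replaced it later. The scan with neighbours removed, the ranks over all distal peaks and the masked share of the strongest were added after that. The limits for calling a test of transcript output, germline nuclei or tlf-1 copies decided were made stricter after their values were known, to allow for their spread. Outside the fixed lists, gene families of at least 8 members sharing a symbol prefix were scanned, and 2 of 171 had promoter peaks more often than other genes. The hmg genes, for high mobility group proteins, had them at 5 of 9 (hmg-1.1, hmg-3, hmg-6, hmg-1.2 and hmg-4), and lin genes at 10 of 44. The latter, a prefix given for a mutant phenotype and not for a shared protein, were lin-66, lin-54, lin-5, lin-7, lin-8, lin-28, lin-35, lin-53, lin-9 and lin-52. Nucleoporin (npp) genes, at 6 of 26, did not pass the adjustment.

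Among 714 IDR peaks over 1000 bp from any coding gene start, 141 lay on X, and some were among the strongest of the set, such as those centred at 11094215 and 6296594, ranked 13 and 15; a candidate explanation is that they are recruitment sites of the dosage compensation complex. Its X motif, recalled from the literature as TCGCGCAGGGAG and sought with up to 2 mismatches in 400 bp, was in 18 of 141 distal X peaks and 6 of 573 autosomal ones, a ratio of 12.2 (p = 3.73e-09, Fisher's exact test), and in 11 of the 20 strongest on X; with up to 1 mismatch it was in 11 against 0, and with up to 3, where 7.25% of random X windows matched, in 26.2% against 16.4% (ratio 1.60, p = 0.0104, Fisher's exact test). Repeats filling at least 50% of the sequence are argued against by a median soft-masked share of 18.1% at all distal X peaks (23.02% at autosomal ones, bootstrap interval of the difference -8.42 to -1.24) and of 28.8% (interval 15.96 to 36.9) at the 13 X peaks among the 20 strongest, where the 7 autosomal ones had 47.1% and the difference is undecided (-36.1 to 12.6). A tRNA gene lay within 100 bp of 29.8% of distal X peaks (interval 22.9 to 37.8) and of 1 of the 20 strongest on X. These values argue against tRNA genes as the source of most distal X peaks or of the strongest. They leave tRNA genes open for the others, since the share was 5.58% at distal autosomal peaks. Chance is argued against by a scan of all cuts of the ranked distal peaks and all chromosomes, with labels permuted peak by peak as if independent (permutation p = 9.99e-04, the smallest possible, also with only the strongest peak within 20 kb kept), but only the top holds the excess: X had 13 of the 20 strongest distal peaks, 19 of 50 and 26 of 100 (26.0% against 18.7% in the rest, exact p = 0.104), and the median ranks of X and autosomal peaks over all 714 gave a permutation p of 0.647. Open remain antibody or chromatin effects that an untagged strain would show, not analysed here.

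The 12 lists called higher, among them cytosolic ribosomal proteins and germline markers, had promoter peaks more often than other genes. Neuron markers and collagens had them less often. Core histones, aminoacyl-tRNA synthetases, and actins and tubulins were not called. Intestine, muscle and hypodermis markers were not called either, with odds ratios of 0.326, 0.245 and 0.491. Their Wilson intervals hold the share of collagens, 1.16%, and that of all coding genes, 5.28%, so they were not shown to differ from either. Both of the following readings of this pattern stay open. High transcript output alone would need peaks at abundant tissue transcripts, and sperm, collagen, muscle and vitellogenin genes had them at 1.34%, against 5.34% of other genes (p = 6.13e-04, Fisher's exact test). Expression was not measured, so whether these transcripts were abundant here is unknown, and the intervals of 3 of these lists reach the overall share. The 172 collagen genes among these 299 are themselves part of the pattern to be explained, so this test cannot decide. Signal from germline nuclei only would make X-linked members of the lists called higher less often bound. The odds ratio there was 1.13 (interval 0.447 to 2.64), from 9 of 30 X-linked genes, too few to tell. Over all coding genes the odds ratio of X to autosomes was 0.407, and germline markers had promoter peaks at 35.6%. Both could be seen under that reading, and neither tests whether germline nuclei were the only source.

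The pooled peaks around tlf-1 could come from extra copies of the transgene. The 28 peaks exceeded 94.6% of windows of that size on chromosome I and equalled or exceeded 95.8%, which straddles the limit set and decides nothing. For the unc-119 rescue, peaks were counted over the gene and 1000 bp each side, a smaller window than for tlf-1. The 2 peaks found exceeded 36.96% of windows of that size on chromosome III and equalled or exceeded 51.8%. These values argue against extra copies as a source of peaks there. The strain of the control is not given in the sources used here, and a control from this strain would cancel both. No biological explanation of the peaks around tlf-1 and unc-119 was tested.

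Distal X peaks held 10 of 2080 6-base words more often than distal autosomal peaks, led by CCCTGC (16.3% against 2.44%), whose complement GCAGGG is part of the X motif. Of the distal X peaks, 42 lay within 100 bp of a tRNA gene, against 32 of the 573 distal autosomal ones. As a class, tRNA genes had peaks at similar shares on X (23.2%) and autosomes (22.02%; odds ratio 1.07, p = 0.771, Fisher's exact test).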
